A study of Mus musculus with 20 samples.

How the data were processed

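RNA was measured by sequencing in mouse abdominal aorta from 20 libraries in 4 groups of 5: wild-type (WT) mice given saline, WT mice given angiotensin II (Ang II) at 500 ng per kg per min, libraries labelled KO given saline, and libraries labelled KO given Ang II. Ang II is the peptide hormone that constricts arteries and raises blood pressure, and the series title names DAPK1, a calcium/calmodulin-dependent serine/threonine kinase. Each library is 1 animal and is named here by its title, in which NS stands for saline and the number for the animal (WTNS_369). The description of the KO saline libraries calls them WT given saline, while their title and genotype call them KO, and the title and genotype were used. Per the labels, RNA was extracted with TRIzol and libraries were made from 1 µg of total RNA with the NEBNext Ultra RNA kit.

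The deposited tables hold FPKM (fragments per kilobase of transcript, scaled to library size) for each transcript, as the authors computed it. The authors' notes name bcl2fastq, FastQC, fastp and the mm10 genome, with no versions; the aligner, the assembler and the program that gave the values are not given in the sources used here. The transcripts are Ensembl transcripts and transcripts that the authors assembled and named MERGE. There were 49773 transcripts in the WT tables, 49714 in the KO Ang II table and 2025 in the KO saline table. Of the 32654 Ensembl transcripts in the WT tables, 32618 were in GENCODE M21 on GRCm38, which gave gene names and positions, as were 32908 of 32945 in the KO Ang II table and 1335 of 1337 in the KO saline table.

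The main tests used no read counts. The values of each library times the transcript length fell on whole multiples of a common step, from which a depth was worked out: 97.9% to 99.1% of the values below 50 reads lay within 0.05 reads of a whole number. The depth worked out this way was 62.8 to 67.1 megareads in WT saline, 59 to 74.4 in WT Ang II, 70.1 to 73.5 in KO Ang II and 69.7 to 74.9 in KO saline. A read on a transcript of 1 kb was then worth about 0.0134 to 0.017 FPKM. The listed values of a library added up to 420123 to 544458 FPKM in WT saline, 417513 to 494104 in WT Ang II, 430833 to 519839 in KO Ang II and 6589 to 7986 in KO saline, whose table holds only part of each library. Among the 15 other libraries MERGE transcripts took 12.2% to 15.8% of that sum.

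The WT and KO Ang II tables each list another set of transcripts. Each transcript in the WT tables had a mean of at least 0.5 FPKM in WT saline or WT Ang II, and each transcript shared with the KO Ang II table had one in WT Ang II or KO Ang II. They shared 46490, of which 30974 were annotated, while 1644 annotated transcripts were in the WT tables alone and 1934 in the KO Ang II table alone. FPKM of annotated transcripts were added up per gene, with a transcript that a table does not list taken as 0. Of 15346 genes listed, 14583 had a transcript in both tables, and the 12643 with a mean of at least 1 FPKM over the 15 libraries were tested, 2218 of them with a transcript unlisted in 1 table. A further 508 genes were only in the KO Ang II table and were not tested. Differences were tested with limma (trend and robust options) on log2(FPKM + 1), with all 15 libraries in 1 model. The Benjamini-Hochberg adjusted p threshold was 0.05, and 3 comparisons were made: WT Ang II against WT saline, KO Ang II against WT Ang II, and KO Ang II against WT saline. On this scale the pseudocount of 1 shrinks the differences of genes with low values. The plan, made before the data were examined, was a model of counts. The planned edgeR model was not used, because the tables hold FPKM, and limma on FPKM took its place. The model used, the sums per gene, the filter and the treatment of unlisted transcripts were chosen after the form of the values was known.

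Before the data were examined, 20 gene lists and 17 lists of cell type markers were fixed, of which 33 had enough measured members to be tested. A member counts as measured if it was among the 12643 tested genes. They were tested with camera in limma with a preset correlation of 0.01, and again with an estimated correlation and with fry, the last of which asks if the genes of a list move on balance one way. Members of a list were also adjusted over the list alone. The rule for named genes, fixed at the same point, takes the targeted gene and, per comparison, up to 8 genes in each direction with the largest change among those that pass, with a mean of at least 1 in the higher group and with all libraries of 1 group above all of the other; it passes over unnamed gene models, immunoglobulin and T cell receptor segments, Xist and Y-linked genes. From each list it takes up to 4 members that pass or, where none does, the 2 with the highest mean, and where fewer than 5 genes pass in a comparison it adds the 5 with the smallest p. Not all genes that the rule takes are reported in the text. Which lists open each comparison, and which genes stand as examples, was chosen after their values were seen.

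The KO saline table overlaps too little with the others for sums per gene. Comparisons with KO saline used the 974 annotated transcripts found in every table, 619 of which had a mean of at least 1 FPKM, in 1 limma model of 20 libraries with the interaction of genotype and Ang II. Of those 974 transcripts 89.2% differed by at least 1 log2 unit between KO saline and KO Ang II, against 41.1% between KO saline and WT saline and 34.8% between KO saline and WT Ang II. In the KO saline table, not only among those 974, 366 transcripts had a KO saline mean under 0.5 FPKM. Of these, 342 were listed for KO Ang II, and 341 had a KO Ang II mean of at least 0.5. A minimum of 0.5 for the higher group mean, as seen in the other tables, would fix this count beforehand. By the 89.2% above, the KO saline transcripts found in every table mainly differ between the KO groups, a choice made on these samples. Names of MERGE transcripts were not compared with KO saline, since across shared names the correlation with the WT tables was -0.047, against 0.844 between the WT and KO Ang II tables.

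Because transcripts of other organs split the libraries, sums of FPKM were taken over intestinal, lung, heart and kidney genes per library, for KO saline over the intestinal transcripts found in every table. These sums, the term for libraries with an intestinal sum of at least 1 FPKM, the marker means used as covariates and the leaving out of libraries high in skeletal muscle markers were chosen after the data were seen. Alternatives fixed beforehand were other scalings and filters, sample quality weights, a minimum change, a model of only the groups compared, leaving out each library, and leaving out the animals numbered below 500. Pseudocounts of 0.1 and 0.01, other treatments of unlisted transcripts, quantile normalization and limma-voom on reads worked out from the values were added after the data were seen. The scalings became median-of-ratios and upper quartile factors on FPKM, and voom with quality weights became limma with quality weights, because the values are not counts. Other splits of the libraries into groups of the same sizes were drawn 100 times per comparison.

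The procedure was tested on simulated data with the spread of each gene and no correlation between genes, in which 100 of the 12643 genes were changed by 1 log2 unit and 100 by 2. At 1 log2 unit it found 61%, 64% and 55% of the changed genes in the 3 comparisons, and at 2 it found 89%, 88% and 91%, with 5, 4 and 4 other genes called. A shift of 0.35 log2 in the 39 collagen and matrix genes was found with camera adjusted p of 0.00185, 0.00514 and 1.91e-05 and no other list was called; genes that vary together, as in the real libraries, were not part of this simulation. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.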

Results

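RNA of the mouse abdominal aorta was compared between WT animals and libraries labelled KO, given saline or Ang II for each, with 5 animals in each of the 4 groups. The depth worked out from the values was 59 to 74.9 megareads per library. WT saline, WT Ang II and KO Ang II could be compared over 12643 genes, and KO saline only over 619 transcripts. Over the 12643 genes, libraries correlated with a mean Pearson's r of 0.911 within groups and 0.907 between groups. All adjusted p are from limma, or from camera in limma for gene lists, and differences are log2 differences of FPKM + 1.

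Dapk1, the gene of the series title (ENSMUSG00000021559.14, chromosome 13, 60601947 to 60763191, plus strand, GRCm38), codes for a calcium/calmodulin-dependent kinase with a part in cell death. Its FPKM were 15.4, 9.48, 10.1, 12.6 and 12.9 in WT saline animals WTNS_369, WTNS_373, WTNS_523, WTNS_547 and WTNS_550, and 9.16, 19.9, 3.96, 9.50 and 11.1 in WT Ang II animals WTAng_II519, WTAng_II536, WTAngII568, WTAngII580 and WTAngII581. In KO Ang II they were 6.91, 10.3, 13.8, 6.85 and 4.997 in animals KOAng_II402, KOAngII537, KOAngII560, KOAngII612 and KOAngII628. The group means were 12.1 ± 2.39, 10.7 ± 5.79 and 8.58 ± 3.51 FPKM (SD, n = 5). KO Ang II differed from WT Ang II by -0.22 (SE 0.32, adjusted p = 0.847) and from WT saline by -0.50 (adjusted p = 0.738). The KO Ang II sums include ENSMUST00000225632 and ENSMUST00000226059, which have no listed WT value, the latter at 13.3 FPKM in animal KOAngII560. The only transcript listed for WT and KO Ang II, ENSMUST00000077453 with 5491 nt, was at 4.51, 9.46, 0.514, 6.51 and 2.73 FPKM in the KO Ang II libraries, and KOAngII560 and KOAngII628 lay below the lowest WT value of 3.96. With only transcripts listed for all 15 libraries the differences were -1.15 for Dapk1, KO Ang II against WT Ang II (adjusted p = 0.674), and -1.44 for Dapk1, KO Ang II against WT saline (adjusted p = 0.438). KO saline has 0 Dapk1 transcripts among those listed in every table. RNA that stays outside a deleted part of a gene would leave these values as they are, so they check neither the label nor the loss of the protein; each direction below that is drawn from the KO label is unchecked.

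**Figure D1:**
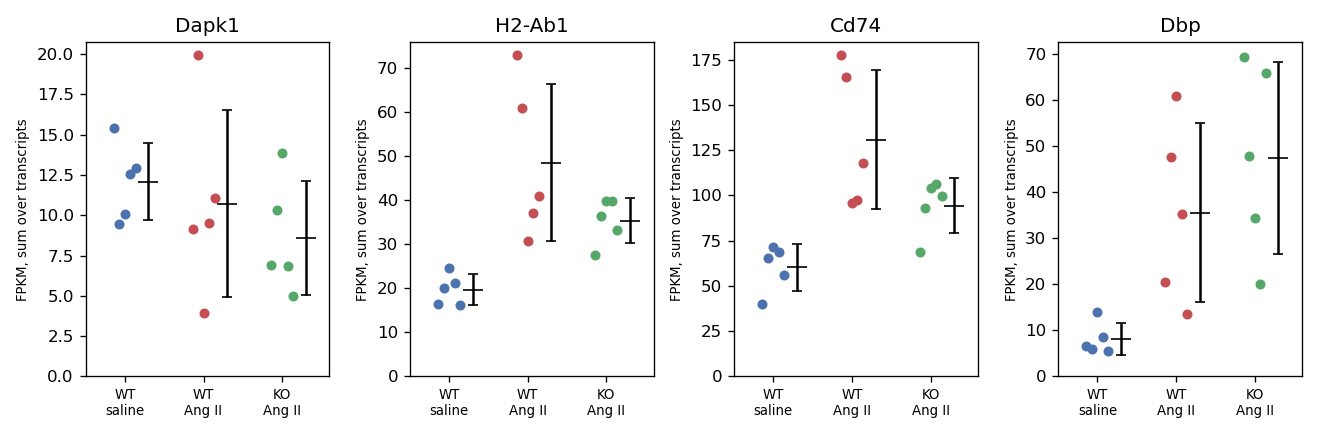
FPKM of Dapk1, H2-Ab1, Cd74 and Dbp in each library of WT saline, WT Ang II and KO Ang II, with bars for the mean and SD of 5 animals. The Dapk1 sums overlap between the groups, with transcripts listed only for KO Ang II included, while H2-Ab1 lies at 16.2 to 24.6 FPKM in WT saline and at 30.7 to 72.9 in WT Ang II.

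WT Ang II was compared with WT saline to ask what the infusion changed in the WT aorta. Genes of MHC class II antigen presentation, with which antigen-presenting cells show peptides to T cells, were higher with Ang II: 6 of the list's 9 genes were measured, all 6 differences were positive, and their median was 1.06 (camera adjusted p = 9.04e-15, and 0.0682 with an estimated correlation). All 6 passed when adjusted over the list alone. H2-Ab1, a class II beta chain on chromosome 17 (34257689 to 34269419), had 19.7 ± 3.51 FPKM with saline and 48.5 ± 17.7 with Ang II (SD, n = 5), and Cd74, the invariant chain on chromosome 18 (60803848 to 60812652), 60.2 ± 12.9 and 130.8 ± 38.4. In both genes each Ang II library lay above each saline library. By fry the list had an adjusted p of 0.0085. Among the 8 libraries without intestinal transcripts (WT Ang II animals WTAng_II519, WTAng_II536 and WTAngII568 and WT saline) its median was 1.196. No single gene passed limma over all 12643: the count was 0, with 618 genes at an unadjusted p under 0.05 where 632 are due by chance. The smallest adjusted p, 0.393, was shared by 6 genes with an SE of 0.17 to 0.34: H2-Ab1 at 1.20, H2-DMa at 1.01, Cd74 at 1.09, Xpo4, a nuclear transport receptor, at 1.76, Fmr1, an RNA-binding protein, at 0.84, and Lsm12, named after its value was seen, at 1.02. Among those 8 libraries 2 genes passed, Xpo4 and Cggbp1, the latter chosen after its value was seen.

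Macrophage markers were higher with Ang II as well. All 17 differences were positive with a median of 0.534 (camera adjusted p = 2.14e-07, and 0.469 with an estimated correlation), and 5 passed adjusted over the list alone: Cd68, Csf1r, C1qa, C1qc and Ms4a7. Lyz2, the macrophage lysozyme, had 132.0 FPKM with saline and 195.9 with Ang II, a difference of 0.56 that did not pass over all genes. Mast cell markers had a median of 0.895 with 5 of 6 positive (adjusted p = 0.00595, and 0.624 with an estimated correlation), among them the protease Mcpt4 at 2.59 and 7.30 FPKM. Interferon response genes had a median of 0.181 (adjusted p = 0.0213), and cytokines, chemokines and adhesion genes 0.18 (adjusted p = 0.0460), and both had 0.624 with an estimated correlation.

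Matrix, contractile and vasoconstrictor lists were higher with Ang II by small amounts, while endothelial and fibroblast markers did not pass. In the collagen and matrix list 33 of 39 differences were positive with a median of 0.338 (camera adjusted p = 4.60e-05, and 0.624 with an estimated correlation). Sparc, a collagen-binding matrix protein, had 1395 and 1845 FPKM. Contractile smooth muscle genes had a median of 0.263 with 17 of 20 positive (adjusted p = 0.0107, and 0.624 with an estimated correlation), with Acta2, the smooth muscle actin (chromosome 19, 34241090 to 34255590), at 5343 and 6335 FPKM. Vasoconstrictor receptors and calcium entry had a median of 0.148, matrix proteases and inhibitors 0.251, and the renin-angiotensin system 0.259, with adjusted p of 0.0107, 0.0213 and 0.0213, and 0.624 for each with an estimated correlation. Chondrogenic and osteogenic genes had a median of 0.357 (adjusted p = 0.0173, and 0.469 with an estimated correlation). With the means of brown adipocyte, sympathetic neuron and skeletal muscle markers as covariates the contractile median turned to -0.03.

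Genes of oxidative metabolism were lower with Ang II, together with markers of tissue around the vessel. All 34 nuclear oxidative phosphorylation genes had a negative difference, with a median of -0.285 (camera adjusted p = 6.95e-07), as had 26 of 28 genes of fatty acid use and lipid synthesis, with a median of -0.426 (adjusted p = 0.000115), and 12 of 13 mitochondrially encoded genes, with a median of -0.402 (adjusted p = 0.00595). With an estimated correlation these 3 lists had an adjusted p of 0.624. Brown adipocyte markers moved with them, with a median of -1.027 (adjusted p = 8.76e-05, and 0.624 with an estimated correlation): Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 842.9 FPKM with saline and 445.1 with Ang II. Sympathetic neuron markers had a median of -1.192 (adjusted p = 0.0103), skeletal muscle markers -0.839 (adjusted p = 0.0198) and white adipocyte markers -0.149 (adjusted p = 0.0477). With an estimated correlation these last 3 had 0.624, 0.624 and 0.645. With the 3 marker means as covariates the medians of the 3 metabolic lists and of white adipocyte markers turned positive. In that direction 2 of them passed camera: nuclear oxidative phosphorylation at 0.123 (adjusted p = 8.59e-05) and white adipocytes at 0.40 (adjusted p = 0.00208). The circadian clock list passed with a median of 0.274 (adjusted p = 0.0493, and 0.624 with an estimated correlation). By fry its adjusted p was 0.481 for changes in 1 direction and 0.0104 for changes in either direction. Over the list alone Nr1d1, Dbp, Bhlhe40 and Bhlhe41 were higher and Cry1 and Nfil3 lower.

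Lists that did not pass in WT Ang II against WT saline were RhoA-ROCK and myosin light chain genes (median 0.048), vasodilator signalling and potassium channels (0.13), oxidative stress and NADPH oxidase (0.046), apoptosis and autophagy (0.138), cell cycle (0.114), immediate early and heat shock genes (0.091), the unfolded protein response (-0.058), and markers of neutrophils (-0.131), B and plasma cells (0.146), endothelium (0.023), fibroblasts (0.142), erythroid cells (0.03), Schwann cells (-0.144) and lymphatic endothelium (0.134). Their adjusted p were 0.0822 to 0.975. T and NK cell markers had 0 of 15 members among the tested genes, and mesothelial, pancreatic acinar, and kidney and adrenal markers had 1 each, so these lists were not tested. The T and NK cell markers had values below the filter. Their mean log2(FPKM + 1) was 0.537 (SD 0.148) in WT saline, 0.783 (SD 0.155) in WT Ang II and 0.635 (SD 0.204) in KO Ang II.

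**Figure D2:**
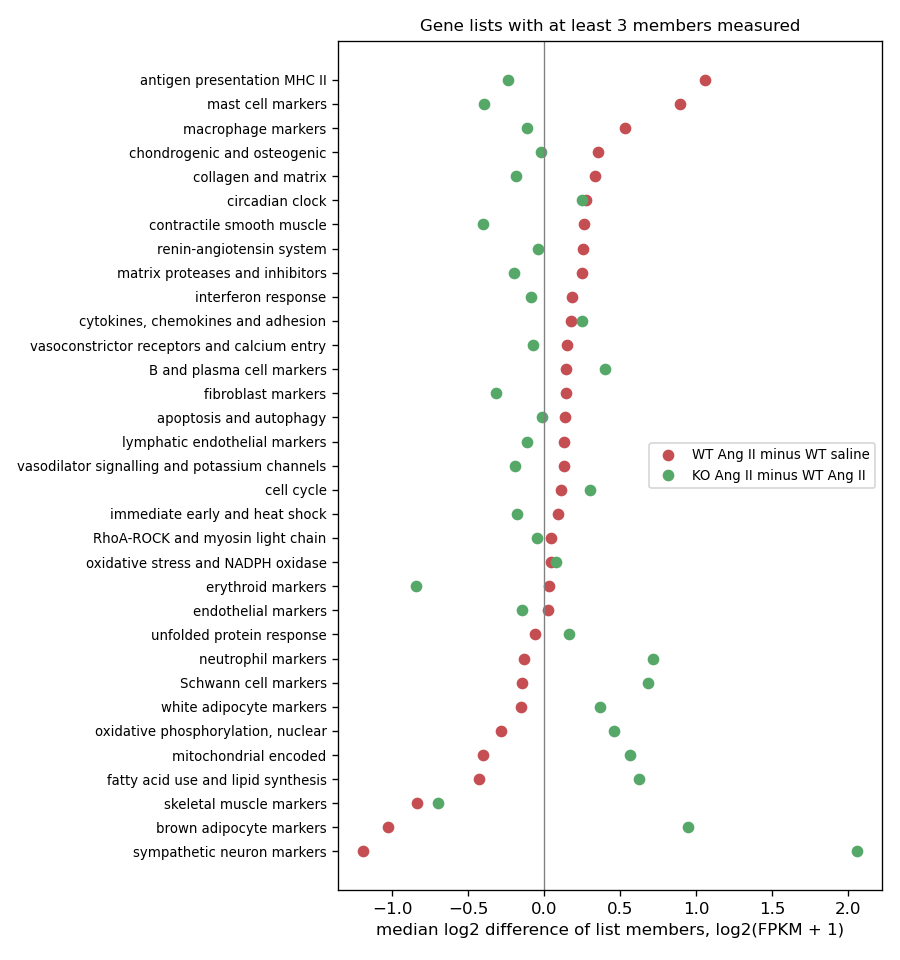
Median log2 difference over the measured members of each of the 33 gene lists, in WT Ang II against WT saline and in KO Ang II against WT Ang II. The MHC class II list lies at 1.06 in the first comparison, and the nuclear oxidative phosphorylation list at -0.285 in the first and 0.46 in the other.

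KO Ang II was compared with WT Ang II to ask what the KO label goes with during the infusion. Genes of oxidative metabolism were higher in KO Ang II: all 34 nuclear oxidative phosphorylation genes had a positive difference, with a median of 0.46 (camera adjusted p = 1.36e-08), 25 of 28 genes of fatty acid use and lipid synthesis had one, with a median of 0.624 (adjusted p = 1.27e-05), and 12 of 13 mitochondrially encoded genes, with a median of 0.568 (adjusted p = 0.00194). With an estimated correlation these 3 lists had an adjusted p of 0.613. Atp5b, a subunit of ATP synthase (chromosome 10, 128083273 to 128090391), had 474.0 FPKM in WT Ang II and 686.8 in KO Ang II, and Scd1, a fatty acid desaturase, 1239 and 2124. Contractile smooth muscle genes were lower, with 17 of 20 differences negative and a median of -0.402 (adjusted p = 0.00194, and 0.613 with an estimated correlation). Acta2 had 6335 and 4431 FPKM. With the 3 marker means as covariates the contractile median was -0.14 and the list no longer passed camera (adjusted p = 0.2305).

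Some markers of tissue around the vessel differed in the same libraries. Skeletal muscle markers went the other way, with a median of -0.699, and did not pass (camera adjusted p = 0.2865). Brown adipocyte markers had a median difference of 0.95 (camera adjusted p = 0.0124), white adipocyte markers 0.368 (0.0215), sympathetic neuron markers 2.06 (0.000466) and Schwann cell markers 0.686 (0.00975), each an adjusted p. With an estimated correlation each had 0.613. Npy, the neuropeptide of sympathetic nerves, had 14.6 FPKM in WT Ang II and 111.7 in KO Ang II, where animal KOAngII537 had 297.7 and animal KOAngII612 had 0.986. Cell cycle genes were higher with a median of 0.303 (adjusted p = 0.0254, and 0.613 with an estimated correlation), which was -0.0327 without animal KOAngII612 (adjusted p = 0.654). Fibroblast markers were lower with -0.314 (adjusted p = 0.0124, and 0.613 with an estimated correlation), and collagen and matrix genes lower with -0.185 (adjusted p = 0.0318, and 0.676 with an estimated correlation). No member of these lists passed over its list alone, and with the 3 marker means as covariates the medians for Schwann cells, white adipocytes and collagen turned to -0.21, -0.27 and 0.19, the last 2 past camera (adjusted p = 0.0263 for each).

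**Figure D3:**
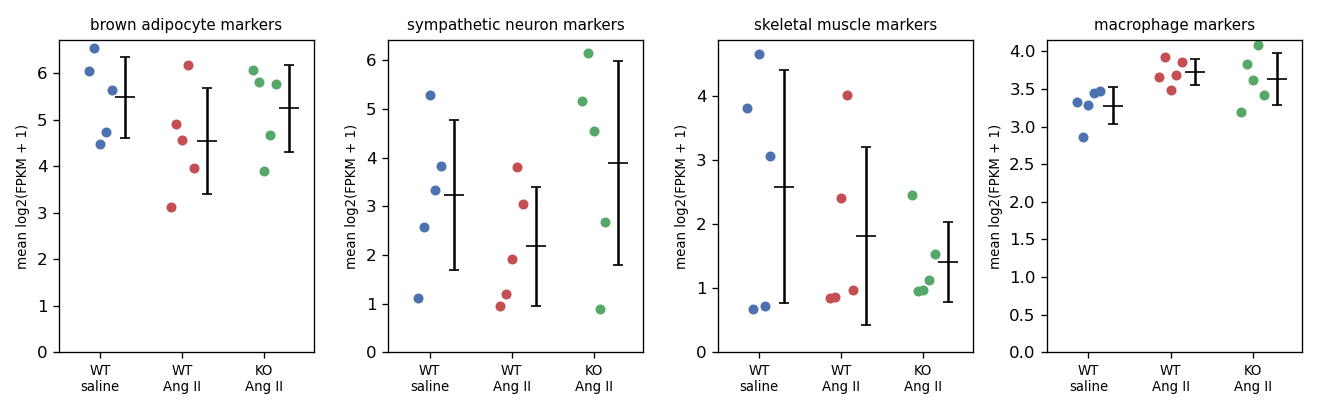
Mean log2(FPKM + 1) of brown adipocyte, sympathetic neuron, skeletal muscle and macrophage markers in each library of WT saline, WT Ang II and KO Ang II, with bars for the mean and SD of 5 animals. Brown adipocyte markers have means of 5.49, 4.55 and 5.25 in these groups with SDs of 0.868, 1.14 and 0.928.

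Over single genes limma called 0 in KO Ang II against WT Ang II, with 1003 at an unadjusted p under 0.05 and a smallest adjusted p of 0.236. That value was shared by 4 genes. Dmtf1, a transcription factor of the cell cycle, had a difference of -0.96 (SE 0.17) with 6.61 and 2.92 FPKM. The others were Zg16, Defa30 and Reg3b, followed by Defa32, none of which passed; they code for intestinal antimicrobial and secretory proteins. KO Ang II libraries and WT Ang II animals WTAngII580 and WTAngII581 carried such intestinal transcripts, and the 3 other WT Ang II animals did not. Among the 7 libraries that carried them the oxidative phosphorylation median was 0.079 and the contractile median -0.21 (camera adjusted p = 0.843 and 0.192), and 6 genes passed, which were chosen for mention after the values were seen: Atg4a, Gm12191, Hnrnpm, Lrrc8a, Rpl30-ps9 and Usp12. Without WT Ang II animal WTAngII580, 7 genes passed, 6 of them intestinal transcripts.

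Lists that did not pass in KO Ang II against WT Ang II included MHC class II (median -0.24, adjusted p = 0.0741), vasoconstrictor receptors and calcium entry (-0.074, 0.0734), RhoA-ROCK and myosin light chain genes (-0.045, 0.478), vasodilator signalling and potassium channels (-0.194, 0.357), the circadian clock (0.247, 0.152) and macrophage markers (-0.112, 0.307). For the renin-angiotensin system the median was -0.04 and the mean 0.006, and apoptosis and autophagy with a median of -0.014 and lymphatic endothelium with -0.113 had tests in the other direction. The 22 lists that did not pass had adjusted p of 0.0528 to 0.949, the lowest for immediate early genes at -0.176 and erythroid markers at -0.845.

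KO Ang II was compared with WT saline to place the infused KO animals against WT animals given saline. Genes past limma numbered 13, with 12 higher and 1 lower, and 1058 had an unadjusted p under 0.05. Most of the 13 were intestinal: Reg3b, Defa24, Defa20, Defa32, Defa21, Defa30, Zg16, Defa2 and Defa22 were listed at 0 in all 5 WT saline libraries and, for Reg3b, at 9.52 ± 2.15 FPKM in KO Ang II (SD, n = 5, adjusted p = 0.0115). The unnamed gene model Gm7849 was listed at 0 there as well (adjusted p = 0.0312; named after its value was seen). Dbp, a clock-controlled transcription factor (chromosome 7, 45705088 to 45710203), rose by 2.36 (SE 0.41) from 8.09 ± 3.48 to 47.5 ± 20.9 FPKM, with each KO Ang II library above each WT saline library (adjusted p = 0.0467). Bcl6, a transcriptional repressor (chromosome 16, 23965052 to 23988852), fell by 0.67 on the log2 scale (SE 0.11) from 24.3 ± 1.34 to 14.98 ± 2.37 FPKM, with 18.1 in WT Ang II (adjusted p = 0.0226). Arrdc1, an arrestin-domain protein named after its value was seen, rose by 1.09 (SE 0.18, adjusted p = 0.0264). Of the refits without 1 library of either group, Dbp passed only in those without WT saline animal WTNS_523 or KO Ang II animal KOAngII612, Bcl6 only in those without WT saline animal WTNS_373 or KO Ang II animals KOAngII560, KOAngII612 or KOAngII628, and Arrdc1 only in those without WT saline animal WTNS_373 or KO Ang II animal KOAngII537. Defa22 and Gm7849 passed only in the refit without KO Ang II animal KOAng_II402, and Defa20 and Defa21 in all but that without KOAngII537. With sample quality weights 30 genes passed, 15 higher and 15 lower. Dbp and Arrdc1 did not pass with only transcripts listed for all 15 libraries, nor with unlisted transcripts at 0.5 FPKM. They did not pass with voom on recovered reads or at a pseudocount of 0.1 either, while Bcl6 passed in these 4 settings. Both calls thus depend on how unlisted transcripts and low values were treated. After quantile normalization none of Dbp, Bcl6 and Arrdc1 passed, and without animal KOAngII537 the count was 7 and without animal WTNS_547 it was 8. It was 1 without the 4 libraries highest in skeletal muscle markers and 0 without the animals numbered below 500.

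Gene lists past camera in this comparison numbered 7. MHC class II was higher with a median of 0.84 and all 6 members positive and past the test over the list alone (camera adjusted p = 3.99e-08, and 0.274 with an estimated correlation). The circadian clock list was higher with a median of 0.605 (adjusted p = 0.00364, and 0.274 with an estimated correlation). By fry for changes in 1 direction the MHC class II and clock lists each had an adjusted p of 0.0535 and did not pass. For changes in either direction the clock list had 0.00104 by fry. Over the list alone 9 members were higher, Per3, Cry2, Nr1d1, Dbp, Tef, Hlf, Ciart, Bhlhe40 and Bhlhe41, while Arntl, the partner of CLOCK, was lower at -1.73 and Nfil3, a repressor of the sites that Dbp activates, at -1.61. Macrophage markers had a median of 0.264 (adjusted p = 0.00111) with Cd68 at 1.44, cytokines, chemokines and adhesion genes 0.61 (adjusted p = 0.00180), Schwann cell markers 0.467 (adjusted p = 0.0160), and cell cycle genes 0.374 (adjusted p = 0.00496), with Top2a, Ccnd1 and Rrm2 past the test over the list alone. With an estimated correlation these 4 lists had an adjusted p of 0.803. Skeletal muscle markers were lower with a median of -1.321 (adjusted p = 0.00301, and 0.803 with an estimated correlation), which turned to 0.54 without the 4 libraries highest in them. These were WTNS_369, WTNS_523, WTNS_550 and WTAngII580, left out for their values of this same list. The rise was thus fixed beforehand and says nothing on the groups. The 26 other lists had adjusted p of 0.124 to 0.753, among them contractile smooth muscle at -0.103, collagen and matrix at 0.149 and nuclear oxidative phosphorylation at 0.135; for RhoA-ROCK genes the median was 0.002 and for vasodilator signalling -0.002, where mean, median and test differ in sign. No library of WT saline carried the intestinal transcripts and all of KO Ang II did, so no value within such a batch can be had; with a term for these transcripts, estimated from WT Ang II alone, 0 genes passed, the clock list had a median of 0.914 with an adjusted p of 0.0564, and MHC class II had 1.076 with 4.79e-06.

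**Figure D4:**
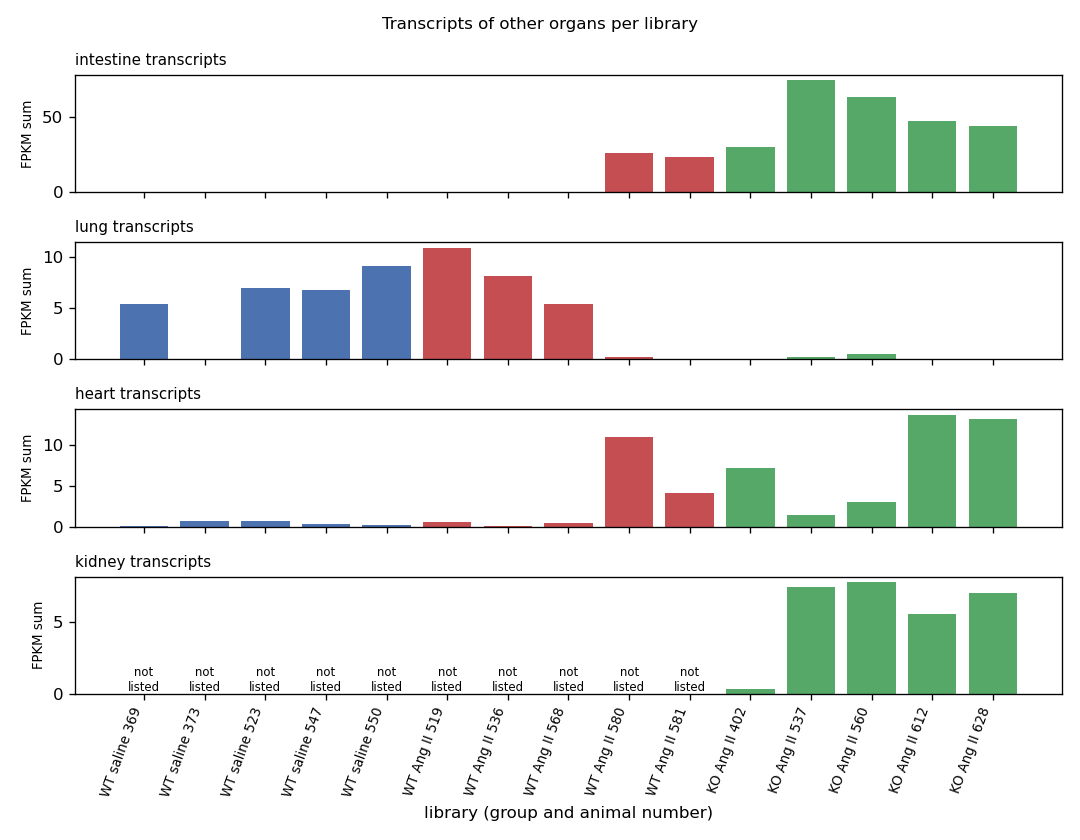
Sums of FPKM over intestinal, lung, heart and kidney transcripts in each library of WT saline, WT Ang II and KO Ang II, as bars; kidney transcripts are not listed for WT. Intestinal transcripts appear in WT Ang II animals WTAngII580 and WTAngII581, at 26.2 and 23.1, and in the 5 KO Ang II libraries, at 30.0 to 74.8.

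KO saline was compared with the other groups over 619 transcripts of a list that was chosen on these samples, so that its counts are no independent evidence. Between KO saline and WT saline 7 transcripts passed limma, 4 higher and 3 lower, with 117 at an unadjusted p under 0.05. A transcript of Oaz1, which inhibits polyamine synthesis, rose by 3.98 (SE 0.73, adjusted p = 0.00407) from 4.24 to 60.1 FPKM, and one of Qsox1, a sulfhydryl oxidase, by 1.71 (adjusted p = 0.000138); one of Stab1, a scavenger receptor, fell by 2.83 (10.52 to 1.67 FPKM). Between KO Ang II and KO saline 123 passed, 55 higher and 68 lower with Ang II, with 381 at an unadjusted p under 0.05. The Oaz1 transcript fell by 4.49 (adjusted p = 0.000618) to 2.62 FPKM, transcripts of Sgcd and Htra3 fell by 2.95 and 3.79, and one of Tgfb1i1 rose by 3.09. Most of the rises with the smallest p were intestinal: Reg3b at 2.96 (adjusted p = 0.000602), Defa30, Defa32, Defa24, Defa2, Defa21, Defa20, Zg16 and Defa22. In KO saline the sum of intestinal transcripts was 32.0 FPKM in animal KONS_627 and at most 0.271 in the 4 others, so that KO saline holds too few libraries with these transcripts for a value among them. The effect of Ang II differed between the genotypes in 13 transcripts, 5 positive and 8 negative, with 232 at an unadjusted p under 0.05; the Oaz1 transcript had an interaction of -4.80 (adjusted p = 0.0187), one of Otop1 of 4.69 (adjusted p = 0.0460) and one of Atp5h of 3.24 (adjusted p = 0.0180). Each of these is 1 transcript of its gene, and the sums over the gene could not be compared. Leaving out 1 library moved the interaction count to 6 without WTAng_II519 and to 111 without WTAngII580, that of KO Ang II against KO saline to 64 without KONS_412, and that of KO saline against WT saline to 3 without KONS_412 and 14 without WTNS_523. For KO Ang II against KO saline it was 13 without animals numbered below 500 and 370 with sample quality weights.

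Across the 12643 genes, the log2 difference of WT Ang II to WT saline correlated with that of KO Ang II to WT Ang II with r = -0.505, over genes that are not independent replicates. WT Ang II enters both differences, and in 100 simulated sets without group effects r averaged -0.495 and ranged from -0.814 to -0.18. When the WT Ang II animals were split in 10 ways so that each difference used other animals, r averaged -0.083 with a range of -0.145 to 0.026. At an unadjusted p under 0.05, 67 genes were higher with Ang II in WT and lower in KO Ang II where 16.4 were due from independent differences, and 58 were lower and then higher where 8.5 were due; the shared group raises both counts.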

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

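The 3 tests of the intestinal transcripts and the tests of the handling batch and of the infusion for the MHC class II genes were chosen after the results were seen; the other tests were written down before theirs.

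Intestinal transcripts set the 5 KO Ang II libraries, KO saline animal KONS_627 at 32.0 FPKM and WT Ang II animals WTAngII580 and WTAngII581 apart from the 12 other libraries, where their sum was at most 0.271 FPKM. Genotype alone is argued against, since 2 WT libraries carried them, the lower at 23.1 FPKM, and 4 of the 5 KO saline libraries did not. Heart and lung transcripts, compared without KO saline, split the same libraries. The heart sum was at least 1.45 FPKM with intestinal transcripts and at most 0.718 without. Lung transcripts were at 5.43 to 10.95 FPKM in 7 of the 8 libraries without and at most 0.55 in the others. The depth worked out from the values also split the libraries this way, again without KO saline. It was 69.3 to 74.4 megareads with intestinal transcripts and 59 to 67.8 without. In KO saline it was 69.7 to 74.9, though 4 of these 5 libraries did not carry them. Carry-over or another shared step of handling is therefore a candidate explanation. Kidney transcripts, not listed for WT, did not follow the split in full. Their sum was 0.314 FPKM in KOAng_II402, which carried intestinal transcripts, and 5.61 to 7.79 in the other KO Ang II libraries. Gut tissue left on the aorta would not by itself split the heart and lung transcripts as given above, which argues against it as the only source. Whether gut tissue had a part beside carry-over cannot be told from the intestinal sums. These differed by 3.24 times between libraries, which lies between the bounds set for the 2 cases.

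Genes of oxidative metabolism were higher in KO Ang II than in WT Ang II, with a median of 0.46 over the nuclear oxidative phosphorylation list. With the brown adipocyte marker mean as a covariate the median was 0.132 (SE 0.018 over members), under 0.5 of its value. That marker list itself holds mitochondrial and lipid genes, among them Cox7a1, Cox8b and Cpt1b. The fall therefore cannot tell a larger share of brown adipose tissue from a rise of such genes within the cells. The oxidative phosphorylation list still passed camera with the preset correlation (adjusted p = 0.000709). Without the covariate its call was already lost with an estimated correlation (adjusted p = 0.613), so this does not settle whether that share is a cause. With a term for the libraries that carry intestinal transcripts the median was 0.079 (SE 0.021 over members) and the camera call ended (adjusted p = 0.907), as the median itself came near 0. Of the 2 WT Ang II libraries that carry them, WTAngII580 had 894.0 FPKM of Atp5b and a brown adipocyte marker mean of 6.183. WTAngII581 had 386.5 FPKM and 3.964, within the 290.4 to 411.5 FPKM and 3.122 to 4.915 of the WT Ang II libraries without them. The term therefore cannot tell the handling batch from the brown adipose tissue of WTAngII580. A difference due to genotype stays open, as the batch term rests on WTAngII580 and WTAngII581 alone on the WT Ang II side.

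MHC class II genes were higher in WT Ang II than in WT saline, with a median of 1.06. The handling batch is argued against, since among the 8 libraries without intestinal transcripts the median was 1.196 (SE 0.069 over members). A larger share of macrophages as the whole cause is argued against as well, as far as the marker mean follows that share. With the macrophage marker mean as a covariate the median was 1.022 (SE 0.035 over members). Camera's adjusted p with the preset correlation was 4.18e-12, and an estimated correlation was not used with this covariate. Both SEs are over the genes of the list and do not measure the spread between animals. Other antigen-presenting cells were not tested. In KO Ang II the list was higher than in WT saline with a median of 0.84, but both comparisons share the WT saline libraries, and low values there alone would raise both medians, so whether the pattern goes with Ang II infusion in both genotypes stays open. As no gene passed alone and the list's call was lost with an estimated correlation (adjusted p = 0.0682), a rise with Ang II is a hypothesis found and tested on the same data.

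Other splits of the libraries were counted, 100 per comparison with the real one included. In WT Ang II against WT saline, 0 genes passed, so that 100 splits gave as many by necessity, with at most 9 genes in another; 19 lists passed, as many only in 1 split, the real one, with at most 16 in another; and an MHC class II median as far from 0 was found in 1 split, the real one, with at most 0.918 in another. The number of lists was thus above that of every other split drawn. It was 1 of several counts compared this way, and 0 lists passed with an estimated correlation, so chance is not excluded. For the MHC class II list alone the real median was also the farthest from 0. That list was chosen after the values of 33 lists were seen, and the largest of the 33 was not tested this way. For single genes there is no result to test. In KO Ang II against WT Ang II, 0 genes passed as well, so that the 100 splits with at least as many say nothing, with at most 806 in another; 46 splits gave at least 11 lists, with at most 21 in another, so chance cannot be excluded for the lists. In KO Ang II against WT saline, 78 splits gave at least 7 lists, with at most 18 in another, so chance cannot be excluded for the lists. For the genes, 2 splits gave at least 13, with at most 184 in another. Most of the 13 were intestinal transcripts, carried by all KO Ang II and no WT saline libraries, and 0 genes passed with the term for them. The splits cannot tell the groups from these transcripts, so the count excludes neither chance nor the handling batch for the other genes. Splits with 806 and 184 genes point to a structure of the samples. The first sets WT Ang II animal WTAngII580 with KO Ang II animals KOAng_II402, KOAngII537, KOAngII612 and KOAngII628 against the rest. These 5 all carry intestinal transcripts, and the 3 Ang II libraries without them, WTAng_II519, WTAng_II536 and WTAngII568, are all on the other side, with WTAngII581 and KOAngII560, so this split follows the intestinal transcripts in part; among the 7 libraries that carry them, KO Ang II against WT Ang II gave 6 genes. With the brown adipocyte marker mean as a covariate that split gave 0 genes. The other sets WT saline animals WTNS_523 and WTNS_550 with KO Ang II animals KOAng_II402, KOAngII537 and KOAngII560 against the rest and kept 179. On that side the sympathetic neuron marker mean was 3.834 to 6.149, and on the other side 0.896 to 3.337. This split thus follows sympathetic neuron markers, which were looked at after the split was seen. Over the KO saline transcripts 1 split gave at least 7, 1 at least 123 and 2 at least 13, with at most 4, 15 and 13 in another; these counts say nothing, because the transcripts were listed for differing between the KO groups.

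A library far from the 4 others of its group was found in 24 of 180 groups of values tested, by a gap to the nearest library of more than 0.71 of the group's range. Chance gives about 1 in 20 for independent values with a normal spread. FPKM were used here without logs and many of these measures vary together, so 24 of 180 cannot be set against that share. WT Ang II animal WTAngII580 had the most of these: MERGE transcripts took 13.01% of its value sum, mitochondrial transcripts 20.73% and the 10 highest transcripts 22.66%, and it had 1351.8 FPKM of Ucp1, 91.9 of Acta1, 1.425 of Xpo4, 894.0 of Atp5b, 460.3 of Acadm and 472.8 of Cidea. In WT Ang II animal WTAng_II536 the mean log2(FPKM + 1) was 3.24 for mast cell markers and 5.716 for endothelial markers, and Mcpt4 had 16.1 FPKM. KO Ang II animal KOAngII560 had a fibroblast marker mean of 7.18, 0.55 FPKM of Scgb1a1 and 3070.04 of Hba-a1. WT saline animal WTNS_369 had a Schwann cell marker mean of 1.953 and 2496.6 FPKM of Hba-a1. In WT Ang II animal WTAng_II519 the Schwann cell marker mean was 1.948, and in WT saline animal WTNS_373 the macrophage marker mean was 2.857. KO Ang II animal KOAngII628 had 98.7% whole values and a mean of 3.086 for B and plasma cell markers. Th had 73.3 FPKM in WT saline animal WTNS_523, Acta1 11.5 in KO Ang II animal KOAng_II402, and Nr1d1 156.7 in WT Ang II animal WTAngII568.

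The effect of Ang II differed between the genotypes in 13 of 619 transcripts by the test of the interaction, over transcripts listed for differing between the KO groups. Outside the comparisons, 508 genes were listed only for KO Ang II.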

How the results depend on the processing

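The tests with tissue covariates, with the term for intestinal transcripts, within libraries with or without them and without libraries high in skeletal muscle markers were chosen after the data were seen, as were the pseudocounts of 0.1 and 0.01, quantile normalization, limma-voom on recovered reads, annotated transcripts in place of sums and other treatments of unlisted transcripts. edgeR and DESeq2 were not run, because FPKM were deposited; the reads worked out from them were tested with limma-voom. No paired analysis was possible because no animal number is shared between groups. Of the values of named genes and lists under alternatives, 3611 kept their direction and side of the threshold, 477 no longer passed, 6 newly passed and 88 turned direction. In WT Ang II against WT saline and KO Ang II against WT Ang II no gene had passed. A gene there that kept its side thus still did not pass, and the tally is no measure of how firm the calls are. For the counts and leading lists, 433 stayed, 65 moved, 17 no longer passed and 2 turned, where a count that changed by a small ratio was taken to have stayed. Under median-of-ratios, upper quartile, quantile and voom scaling WT Ang II against WT saline and KO Ang II against WT Ang II kept 0 genes, and KO Ang II against WT saline had 15, 13, 10 and 16. For the values given here the cause was not tested, except that fits with fewer libraries test with less.

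With the means of brown adipocyte, sympathetic neuron and skeletal muscle markers as covariates, these differences of WT Ang II to WT saline turned: Acadm 0.0933, Ace -0.0778, Acta1 0.12, Acta2 -0.12, Atp2a2 -0.14, Atp5b 0.0646, Bgn -0.0624, Cfd 0.42, Cidea 0.0142, Cox4i1 0.17, Fabp4 0.26, mt-Co1 0.0457, mt-Cytb 0.0789, Scd1 0.18, Tagln -0.0209 and, as Vcam1, WT Ang II against WT saline, -2e-04, and the medians of the lists for brown adipocytes 0.0276, contractile smooth muscle -0.0307, fatty acid use 0.12, mitochondrial encoded genes 0.0457, nuclear oxidative phosphorylation 0.12 (past camera, adjusted p = 8.59e-05), skeletal muscle 0.0024 and white adipocytes 0.40 (past camera, adjusted p = 0.00208); 8 lists passed. For KO Ang II against WT Ang II, Bgn 0.12, Cfd -0.67, Npy -0.18 and Pmp22 -0.24 turned, as did the lists for collagen and matrix 0.19, Schwann cells -0.21 and white adipocytes -0.27, the first and last past camera (0.0263 each), and the contractile list at -0.14 no longer passed. For KO Ang II against WT saline, Pmp22 -0.11 turned and 1 gene passed, Bhlhe40. Brown adipocyte and skeletal muscle lists, and members such as Cidea, Acta1 and Npy, were fitted here with the mean of their own list. Their move toward 0 was thus built in and says nothing. The brown adipocyte list also holds metabolic genes such as Cpt1b, so the moves of the metabolic lists could be built in in part.

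Without the 4 libraries with a skeletal muscle marker mean of at least 3, in KO Ang II against WT saline Acta1 was 1.16, Vcam1 -0.0445 and the skeletal muscle list 0.54, with 1 gene past limma; in WT Ang II against WT saline Acta1 was 0.92, Cytl1 -0.0135 and that list 0.58, with 2 genes; in KO Ang II against WT Ang II Pcna was -0.0157 and Pmp22 -0.11. Without the 6 libraries with a mean of at least 2, Acta1 was 0.68, Vcam1 -0.0168 and the list 0.28 in KO Ang II against WT saline, Acta1 0.49, Dapk1 0.20 and the list 0.14 in WT Ang II against WT saline, and Mcm6 -0.0677 and Pmp22 -0.25 in KO Ang II against WT Ang II. In each comparison with WT saline 1 gene passed, B4galt1. Libraries were left out for their values of the skeletal muscle list, so the turns of that list and of its member Acta1 were built in. Without animals numbered below 500, Acta2 -0.0856, Atp2a2 -0.20, Cfd 0.44, Kit -0.029 and the white adipocyte list 0.13 turned in WT Ang II against WT saline, where 8 lists passed, and Pmp22 -0.15 in KO Ang II against WT saline, where 0 genes passed; the interaction had 3 transcripts and KO Ang II against KO saline 13.

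With an estimated correlation 0 lists passed in each comparison, at unchanged medians: MHC class II 1.06 in WT Ang II against WT saline (adjusted p = 0.0682) and 0.84 in KO Ang II against WT saline (0.274), the clock 0.605 there (0.274), macrophage markers 0.534 (0.469), contractile smooth muscle -0.402 (0.613) and nuclear oxidative phosphorylation 0.46 (0.613). By fry 1, 0 and 0 lists passed, and these medians had adjusted p of 0.0535 for MHC class II 0.84 and the clock 0.605, 0.385 for macrophage markers 0.534, and 0.531 for contractile -0.402 and oxidative phosphorylation 0.46. By fry for changes in either direction 1, 0 and 1 lists passed, the clock in both comparisons with WT saline (0.0104 and 0.00104).

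With the term for intestinal transcripts, C1qa -0.19 turned in KO Ang II against WT saline, where 0 genes and 13 lists passed and the clock list at 0.914 did not (adjusted p = 0.0564); in KO Ang II against WT Ang II Cfd -0.14, Cox4i1 -0.0311, Mcm6 -0.10 and the white adipocyte list -0.0308 turned, contractile -0.21 (0.128) and oxidative phosphorylation 0.0793 (0.907) no longer passed, and 5 lists did. Within the libraries that carry these transcripts the last comparison gave the same values for Cfd -0.14, Cox4i1 -0.0311, Mcm6 -0.10, the white adipocyte list -0.0308, contractile -0.21 (0.192) and oxidative phosphorylation 0.0793 (0.843), with 6 genes and 2 lists; within the others WT Ang II against WT saline had 2 genes. With sample quality weights C1qa -0.0114 and Pcna -0.0526 turned in KO Ang II against WT saline, with 30 genes and 13 lists, Mcm6 -0.0534 and Pcna -0.0815 in KO Ang II against WT Ang II, the interaction had 109 transcripts and KO Ang II against KO saline 370.

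With at least 1 FPKM in 5 libraries the interaction had 23 transcripts and KO saline against WT saline 13; with no filter 39 and 14; with a pseudocount of 0.1 8 and 4. At a pseudocount of 0.01 the interaction had 4 and KO Ang II against WT saline 0; with upper quartile scaling the interaction had 20. With voom on recovered reads Kit was -0.0223 in WT Ang II against WT saline. KO Ang II against WT Ang II had 11 of the 619 transcripts found in every table, in a model of all 20 libraries, so that libraries, unit and transcripts all changed at once, and 1 on annotated transcripts, where WT Ang II against WT saline had 2. With WT Ang II split, the correlation of both differences was -0.083.

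Leaving out 1 library at a time, values ranged as follows. In WT Ang II against WT saline: Ace -0.0242 to 0.14, Atp2a2 -0.10 to 0.17, Cfd -0.28 to 0.22, the white adipocyte list -0.35 to 0.0686, -0.0043 to 0.29 for Csf1, WT Ang II against WT saline, genes 0 to 1 (1 without WTNS_550), lists 10 to 18 (10 without WTAng_II536 or WTNS_373). KO Ang II against WT Ang II had Cfd -0.0836 to 0.55, Dapk1 -0.49 to 0.0265 (0.0265 without WTAng_II536), Mcm6 -0.19 to 0.34, Pcna -0.10 to 0.11, Pmp22 -0.11 to 0.53, the cell cycle list -0.0327 to 0.39, genes 0 to 7 (7 without WTAngII580, 2 without WTAngII581). KO Ang II against WT saline had -0.52 to 0.0081 for Mcm6, KO Ang II against WT saline, Pcna -0.0837 to 0.13, Vcam1 -0.18 to 0.19, genes 7 to 15 (7 without KOAngII537, 8 without WTNS_547), lists 6 to 11 (11 without KOAngII612 or WTNS_373). The interaction had 6 to 111 transcripts, with 111 without WTAngII580, 27 without WTNS_547 or KOAngII560, 35 without WTNS_523 and 6 to 8 without WTAng_II519, WTNS_369, WTNS_373 or KONS_555, KO Ang II against KO saline 64 to 132, with 64 to 79 without KOAng_II402, KOAngII537, KOAngII612, KONS_387, KONS_412 or KONS_627, and KO saline against WT saline 3 to 14, with 3 without KONS_412, 14 without WTNS_523 and 11 without WTNS_547.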

Other observations

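Every test named here was chosen after the data were seen. Gli1, a transcription factor of hedgehog signalling, was listed only in the WT tables, so it had no value in KO Ang II and was not among the 12643 genes. It had 1.83 to 4.01 FPKM in the 5 WT saline libraries (mean 2.95, SD 0.818) and 0.025 to 1.20 in the 5 WT Ang II libraries (mean 0.289, SD 0.509). In a limma model of the WT tables alone the difference was -1.66 (SE 0.25) with an adjusted p of 0.284 over 12551 genes, which did not pass.

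Among the genes listed only for KO Ang II were more genes of the gut and the kidney. Kap, a kidney androgen-regulated protein, had a mean of 4.13 FPKM with a range of 0 to 6.49, Reg3g, an intestinal lectin, 3.69 with a range of 2.43 to 4.95, Fabp6, the bile acid binding protein of the ileum, 2.55, and Defa36, a defensin, 2.15. Krt8, an epithelial keratin, had 1.89 and Ptx3, a pentraxin, 3.22 with an SD of 6.78 from 5 libraries. These genes have no listed WT value and were not compared.

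Transcripts that the authors assembled, outside the annotation, numbered 9184 with a mean of at least 1 FPKM under shared names, and limma called 0 of them in each of the 3 comparisons of WT saline, WT Ang II and KO Ang II. At an unadjusted p under 0.05 there were 485 in WT Ang II against WT saline, 592 in KO Ang II against WT Ang II and 535 in KO Ang II against WT saline. The smallest adjusted p were 0.19, 0.0656 and 0.163.

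The sympathetic genes Npy, Dbh and Th were among the genes that weigh most on the 2 axes of largest variance, which held 18.9% and 12.5% of it. The sympathetic neuron marker mean was 3.23 with an SD of 1.54 in WT saline, 2.18 with an SD of 1.22 in WT Ang II and 3.89 with an SD of 2.10 in KO Ang II. Skeletal muscle markers had means of 2.59, 1.82 and 1.41 with SDs of 1.81, 1.39 and 0.627, and Acta1, the skeletal muscle actin, ran from 0.476 FPKM in WT saline animal WTNS_547 to 95.9 in WT saline animal WTNS_523. The hour at which the animals were killed, which bears on clock genes such as Dbp and Arntl, is not given in the sources used here.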
